A study of Arabidopsis thaliana with 2 samples.

How the data were processed

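Degradome libraries (parallel analysis of RNA ends) were made from 12-day-old Arabidopsis seedlings of the Columbia wild type (WT) and of ago1-27, grown on agar medium at 22 °C with 16 h of light and 8 h of dark, per the labels' protocols. Each library was made from 75 µg of total RNA and read on an Illumina HiSeq instrument, per the labels' protocols. The labels state 3 biological replicates per genotype, but the deposited table of each genotype holds 1 column of counts, so the replicates were treated as pooled and each group counted as 1 library. The deposited values are raw counts, 1 whole number for each distinct tag sequence, with no gene name or position attached. Adapter removal and the collapse of identical reads were inferred from the values, which list each sequence once. The genome build TAIR10 is named per the submitters' processing notes, and the aligner and the trimming tool are not given in the sources used here.

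All positions were found anew. The first 20 nt of each tag were matched without mismatches to the genome and transcripts of assembly TAIR10.1 with RefSeq annotation, and every coordinate printed is a position on that assembly, counted from 1. Tags shorter than 20 nt were left out of the matching. Each tag was put in the first class that applied, in the order organelle genome, nuclear rRNA, more than 10 genome places, snoRNA, snRNA, tRNA, MIR gene, protein-coding transcript in sense, other gene, other sequence. Tags at more than 10 genome places were left out of gene counts, a limit set after the data were examined. Values were scaled per 1000000 tags matching nuclear protein-coding transcripts in sense, of which there were 48267262 in WT and 56316091 in ago1-27. Of these, 45294827 and 53123143 tags matched 1 gene.

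The miRNA part used 50 mature miRNA and tasiRNA sequences and 137 known targets in 38 families, both written down from general knowledge before the data were examined. All 50 sequences were found in the genome. A site was kept where its penalty was at most 4, with 1 for a mismatch, 0.5 for a G:U pair and double weight at miRNA nucleotides 2 to 13. The cleavage position is the base opposite miRNA nucleotide 10, the first base of the downstream fragment. A site entered the comparison with 10 or more tags at that exact position in either library, and a tag that matched several genes was counted at each, though identical tags counted as 1 distinct site. The cleavage share is the number of tags at the site over all sense tags of the transcript, for transcripts with 50 or more tags in both libraries. As background, the 50 sequences were shuffled 100 times and searched in the same way against the highest position of each transcript.

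Gene values are sense tags matching 1 gene, for nuclear protein-coding genes with 100 or more tags in either library, while list members needed 10 or more. Log2 ratios carry 0.5 tag added to each library before scaling, and ratios without a log are not adjusted. Intervals are 95% intervals. Ratios have exact conditional binomial intervals, shares have exact Clopper-Pearson intervals, and shares of tag classes have Wilson intervals. Medians have order-statistic intervals over the members. Tags carry no molecular identifiers, so these intervals and the limit of 3 counts used for a count of 0 cover counting error only. No test was run and no p-value is given, because there is 1 pooled library per group. The median of each list was placed as a percentile among 10000 random lists of the same size, matched on mean tags in bins of 0.5 on the log2 scale, as a description of these 2 libraries. Percentiles below 2.5 or above 97.5 are called outside the central range.

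Before the data were examined, 15 gene lists were fixed. They cover RNA silencing machinery, RNA decay, photosynthesis, the circadian clock, salicylic acid and defence, jasmonate, anthocyanin and flavonoid synthesis, abscisic acid and cold, early auxin response, heat shock, housekeeping genes, markers of root, flower, seed storage and senescence. The 137 miRNA targets were also treated as a list over all their sense tags. A further 5 lists (phosphate starvation, the FLC family, copper proteins and uptake, day phase, dusk phase) were chosen after the values were seen. The rule for the genes named was fixed before the data were examined. It takes the 25 cleavage sites with the most WT tags, the 5 with the most among those higher in ago1-27, the 10 genes with the highest and the 10 with the lowest ratio, from each list the 2 most abundant members and the 2 with the largest ratio either way among members with 100 or more tags, and AGO1. 1 gene that the rule takes from these lists is not reported here. Other genes named were chosen after their values were seen.

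Positional measures used the isoform with the longest coding sequence of each gene. They are the share of coding tags in each reading frame, the share of tags in untranslated and coding parts, the density 26 to 30 nt upstream of exon junctions over the mean of 41 to 100 nt upstream, and the density 16 and 17 nt upstream of the stop codon over the mean of 31 to 80 nt upstream. MIR precursors were scored by tags that start at the ends of the mature miRNA or its star strand, with each tag counted once over all MIR genes. AGO1 coding tags with 1 mismatch were compared with the reference to check the labels.

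The count, interval and list steps were tested on simulated data. Among 17325 genes drawn from the observed means and library sizes, 100 of 100 genes with a 4-fold and 100 of 100 with a 3-fold change were found at 2-fold or more, 0 unchanged genes were called, and 95.4% of intervals held the true ratio. All 50 of 50 planted cleavage sites were found, but these were exact complements in random sequence without tags. Of 200 random lists, 3.5% fell outside the central range. Apart from the planted changes, the simulations held counting error only. Counting alone gave log2 ratios a standard deviation of 0.087, against 0.474 in the data. The simulations therefore check the calculations and not the calls made on these libraries. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.

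The alternatives fixed beforehand were other scalings (all tags, median of ratios), 5′ ends within 1 nt, site minimums of 5 and 50 tags, penalties of 3 and 6, tags matching 1 gene, tags matched over their full length (here over the first 21 nt of tags that long), another share denominator and minimum, gene minimums of 10 and 500 tags, omission of the most abundant position, equal sharing of tags among genes, list members with 100 tags, and equal weight for each transcript. After the data were examined, 6 more were added. They were no limit on genome places, random positions matched also on distance from the transcript end, random genes matched also on length, equal sharing of tags within the lists, only the last 500 nt of transcripts, and the tags within 250 nt of a site as denominator. Organelle, rRNA, snoRNA, snRNA and tRNA tags were left out of all gene comparisons, because the method is meant for polyadenylated nuclear RNA.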

Results

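Degradome sequencing reads the 5′ ends of uncapped, polyadenylated RNA, so that each tag starts where a transcript was cut or where its decay had stopped. A cut directed by a miRNA appears as tags stacked on 1 position, opposite nucleotide 10 of the miRNA. The libraries came from 12-day-old seedlings of 2 genotypes, the Columbia wild type (WT) and ago1-27, a mutant with a weakened allele of AGO1, the Argonaute protein that holds most plant miRNAs and cuts their targets. Each genotype had 1 pooled library, so no difference below has a replicate check, no test was run, and all intervals are 95% intervals that cover counting error only. The WT library held 92257425 tags of 16876911 distinct sequences and the ago1-27 library 101039533 tags of 17843384 distinct sequences. Tags of 20 nt made up 54.4% of the WT and 54.9% of the ago1-27 library, and tags of 21 nt 43.9% and 42.8%. Nuclear protein-coding transcripts took 53.1% of the tags of 20 nt or more in WT and 56.9% in ago1-27, while chloroplast sequence took 25.2% and 17.6%.

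AGO1 (AT1G48410, chromosome 1, 17885633 to 17892632, TAIR10.1) was examined first, since it carries the mutation. A C-to-T change in its coding sequence was present in 148 of 151 tags over the position in the library labelled ago1-27 (98.0%, exact interval 94.3 to 99.6), but in 0 of 112 WT tags, which allows a share of up to 2.68%. The change is C2981T at chromosome 1 position 17886457, with coding bases counted from the first base of the start codon of the longest isoform. It gives the protein change A994V in that isoform. Total AGO1 tags were slightly higher in ago1-27, at 15526 tags in WT and 21748 in ago1-27, a ratio of tags per 1000000 of 1.20 (1.18 to 1.23).

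The first comparison asks how far cleavage of known miRNA and tasiRNA targets differs between the mutant and the wild type. Tags at the cleavage sites were lower in ago1-27 at 71 of 85 distinct sites in 28 families and higher at 14. The sites with larger deficits included the miR168 site of AGO1 itself, all 5 miR393 sites, among them those of the auxin receptor genes, and 8 of 8 miR169 sites in NF-YA genes, which encode DNA-binding subunits of a CCAAT-box factor. By contrast, the sites in HAM1, NAC1 and TAS1C were somewhat higher in ago1-27. The median log2 ratio over the 85 sites was −0.96 (−1.38 to −0.63). It lay at percentile 0 of 10000 random lists of non-target positions, whose central 95% ran from −0.05 to 0.29. At 42 sites the value was at least 2-fold lower in ago1-27 and at 1 site at least 2-fold higher, and the interval of the ratio lay below 1 at 63 sites, above 1 at 11 and held 1 at 11. Random positions matched also on their distance from the transcript end, a choice made after the data were seen, had a central range of −0.18 to 0.13 and again left the sites at percentile 0. Of the 137 listed targets 104 had a site within the penalty limit, and sites above it, such as those of CCS (3030 and 3520 tags), CSD1 (780 and 960), ARF6 (423 and 445) and TCP2 (85 and 66), did not enter. With a penalty of at most 6, 95 sites entered, of which 78 were lower and 17 higher. The number at least 2-fold lower stayed at 42, so the sites above the limit added no such deficit.

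**Figure D1:**
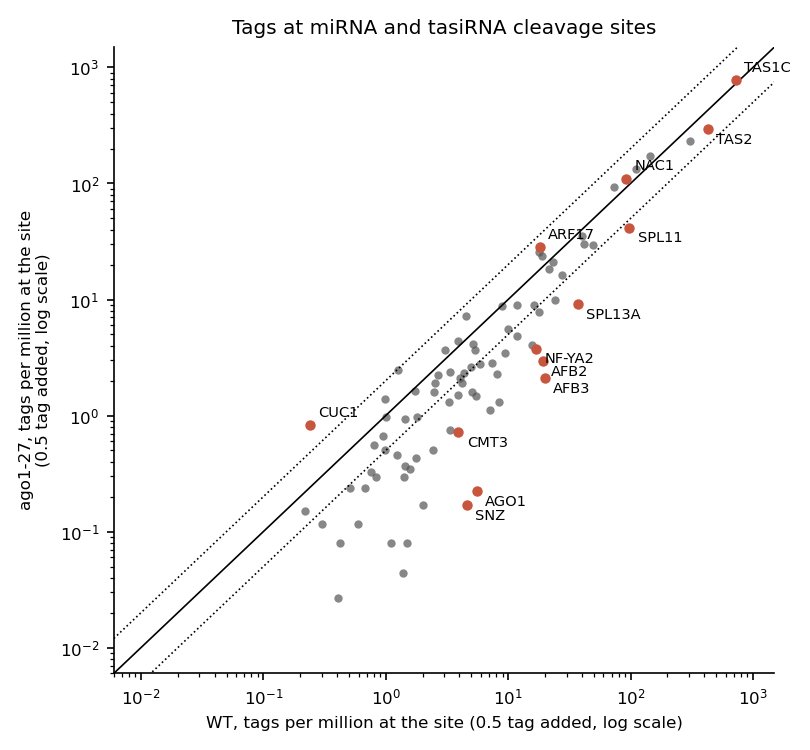
Tags per 1000000 at each of the 85 distinct cleavage sites in WT (x axis) and ago1-27 (y axis), both on log scales with 0.5 tag added, where each point is a site, red points are named, the solid line marks equal values and the dotted lines a 2-fold difference. Most points lie below the solid line (71 of 85), with AGO1, AFB2 and AFB3 far below it and TAS1C and NAC1 just above it, while CUC1 alone lies above the upper dotted line.

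The miR168 site in the AGO1 coding sequence (exon 2, TTCCCGAGCTGCATCAAGCTA, 17891529 to 17891549, cleavage position 17891538) had 268 tags in WT and 12 in ago1-27, a ratio of 0.0384 (0.0196 to 0.0682). The site held 1.73% of AGO1 tags in WT (1.53 to 1.94) and 0.0552% in ago1-27 (0.0285 to 0.0963), and its rank among AGO1 positions went from 5 to 451. AGO1 tags outside the site were 1.22-fold higher in ago1-27 (1.20 to 1.25). The site lies 3048 nt from the transcript end, but the 250 nt on either side of it had 77 tags in WT and 103 in ago1-27, a log2 ratio of 0.19.

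The 5 miR393 sites, of which those in TIR1, GRH1, AFB2 and AFB3 lie in auxin receptor genes, together had 2985 tags in WT and 612 in ago1-27, a ratio of 0.176 (0.161 to 0.192), although tags elsewhere in these transcripts were near equal (0.963). In AFB3 (AT1G12820, chromosome 1, cleavage position 4369094, exon 4 of the coding sequence) the site had 964 and 118 tags, a ratio of 0.105 (0.0859 to 0.127), and its share of AFB3 tags was 15.4% in WT and 1.94% in ago1-27. The ratio was 0.153 (0.129 to 0.181) in AFB2, 0.263 (0.226 to 0.305) in GRH1 (750 and 230 tags) and 0.311 (0.241 to 0.398) in TIR1 (245 and 89 tags). The fifth miR393 site, in the bHLH gene AT3G23690, had 97 and 9 tags.

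**Figure D2:**
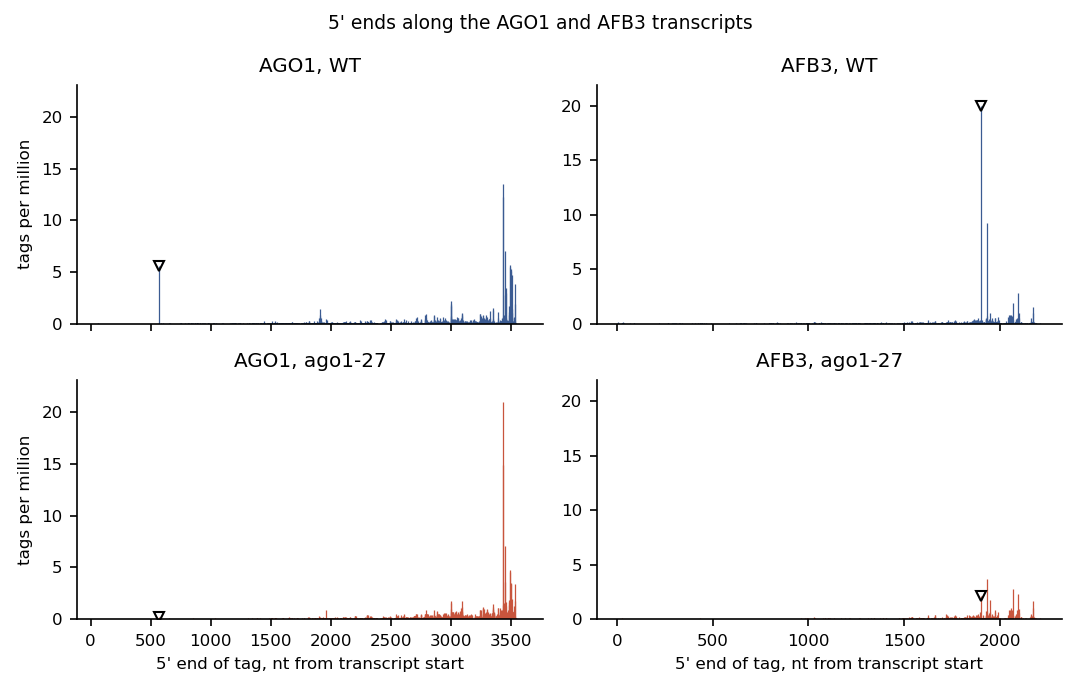
Tags per 1000000 (y axis) by the position of their 5′ end along the AGO1 and AFB3 transcripts in nt from the transcript start (x axis), with WT above and ago1-27 below on the same scale for each gene, where each vertical line is a position and the triangle marks the miRNA cleavage position. At the triangles AGO1 had 268 tags in WT and 12 in ago1-27, and AFB3 964 and 118, while the tags near the 3′ ends of both transcripts were present in both libraries.

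Most NF-YA genes differed in both parts of the transcript. Their 8 miR169 sites had 2775 tags in WT and 891 in ago1-27, a ratio of 0.275 (0.255 to 0.297), whereas tags elsewhere, summed over the transcripts, were 2.77-fold higher in ago1-27, to which NF-YA2 gave the largest part. NF-YA2 (AT3G05690, chromosome 3, cleavage position 1676816 in the 3′ UTR) had 815 and 212 site tags, a ratio of 0.223 (0.191 to 0.260), and 5.21-fold more tags outside the site in ago1-27 (4.92 to 5.52). Its site held 34.5% of the transcript's tags in WT and 2.37% in ago1-27. Outside the site NF-YA3 had a ratio of 2.32 and NF-YA1 of only 1.19 (1.08 to 1.30), and in NF-YA9 the interval of 0.927 to 1.31 held 1. Among the miR156 targets, the SPL genes that time the change from juvenile to adult growth, 9 of 10 distinct sites were lower in ago1-27 and tags elsewhere, summed over the transcripts, were 1.55-fold higher. The log2 ratio at the site was −2.02 for the tags shared by SPL13A and SPL13B (1780 and 510 tags), −1.23 for SPL11 (4725 and 2343), −0.45 for SPL2 (2000 and 1709) and −0.17 for SPL3 (1926 and 1998). In SPL2 the position 1 nt away, opposite nucleotide 10 of miR157, had more WT tags and a log2 ratio of −1.35 (2756 and 1260 tags). SPL10 was the exception at 0.54 (855 and 1446 tags). In SPL3 the tags outside the site were 4.72-fold higher in ago1-27 (4.30 to 5.20), and the share at the site was 76.8% in WT and 39.1% in ago1-27, but the tags outside the site were lower in SPL11, at 0.851-fold (0.784 to 0.924), and near equal in SPL13A, at 1.03-fold with an interval that held 1.

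Several families with many tags differed less or went both ways. The miR173 sites of the TAS1 and TAS2 RNAs, noncoding precursors of tasiRNAs, had log2 ratios of 0.11 in TAS1C (34849 and 43954 tags), −0.54 in TAS2 (20595 and 16488) and −0.40 in TAS1A (14779 and 13046). Both miR171 sites of HAM1, a regulator of shoot meristems, were higher in ago1-27, by 0.26 (6962 and 9755 tags) and 0.24 (5398 and 7445). Of the HAM2 sites, the one cut by miR171b was higher at 0.35 (3563 and 5284 tags) and the one cut by miR171a lower at −0.24 (1033 and 1022). The miR164 site of NAC1, a NAC transcription factor of root branching, was higher at 0.26 (4415 and 6179 tags). The miR160 targets, repressive auxin response factors, had 0.63 in ARF17 (878 and 1589 tags), −0.87 in ARF10 (783 and 501) and −1.21 in ARF16 (867 and 438). The miR172 targets, AP2-like repressors of flowering, had 0.33 in TOE2 (915 and 1338 tags) and −0.76 in RAP2.7 (1341 and 924). No family total changed direction between the scalings tried.

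Other sites among the 25 with the most WT tags were lower in ago1-27. They were the miR824 site of AGL16, a MADS-box gene of stomatal development (2367 and 1649 tags, log2 ratio −0.74), the miR165/miR166 site shared by PHV and PHB, which specify the upper leaf side (1164 and 557, −1.29), and the miR403 site of AGO2 (1126 and 1187, −0.15). All tags at the sites of AGL16, SPL2 and TOE2 also matched a second gene, so the values of these 3 sites may not be the named gene's own. Smaller sites with a ratio chosen after the values were seen were those of the miR172 target SNZ (222 and 9 tags, −4.77), the DNA methyltransferase gene CMT3 (189 and 40, −2.45) and NF-YA1 (66 and 2, −4.96). The 1 site at least 2-fold higher was that of CUC1, a gene of organ boundaries, with 11 and 46 tags and a ratio of 3.58 (1.83 to 7.67). In SNZ the tags outside the site were also lower, at a ratio of 0.199 (0.167 to 0.236).

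The share of a transcript's tags at its cleavage site removes differences in the total tags of the transcript, whose abundance was not measured. A share can also fall because tags elsewhere rise, as in SPL3, with a ratio of 0.889 at the site and 4.72 outside it. The share was lower in ago1-27 for 73 of 82 sites in transcripts with enough tags, among them those of all named NF-YA, AFB and TIR1 genes, and at least 2-fold lower for 33. A transcript with several sites, such as HAM1, entered with each of them. No share was 2-fold higher. The median share was 23.5% in WT and 10.9% in ago1-27, and the median log2 ratio of shares was −0.74 (−1.06 to −0.39). Of these 82 sites, 56 were the position with the most tags of their transcript in WT and 51 in ago1-27. With only the tags within 250 nt of the site as denominator, a comparison added after the data were seen, 68 of 83 sites were lower and the median log2 ratio was −0.86 (−1.27 to −0.39).

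A search with no target list gave a background for these counts. In WT the position with the most tags fitted 1 of the 50 miRNA or tasiRNA sequences in 65 transcripts, of which 56 were listed targets, and in ago1-27 in 47 transcripts, of which 44 were listed. The shuffled sequences gave a mean of 0.03 such transcripts in WT and 0.01 in ago1-27, and never more than 1 in 100 shuffles. Transcripts outside the list in WT included the bHLH gene AT1G10120 with a miR396a site (1563 tags in WT and 948 in ago1-27) and 2 genes with a miR400 site, AT3G16710 (87 and 5 tags) and AT3G22470 (38 and 2 tags). These 3 were chosen after their values were seen.

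The second comparison concerns the tags of whole genes, a measure of RNA decay that follows transcript abundance only in part. FLC, MAF4 and MAF5, which are related floral repressor genes, and genes of light harvesting stood among those higher in ago1-27. Genes induced by phosphate starvation stood among those lower. The floral repressor FLC (AT5G10140, chromosome 5, 3173382 to 3179448) had 85 tags in WT and 1101 in ago1-27, a ratio of 11.1 with a lower interval bound of 8.90. Its relatives MAF5 (10 and 661 tags, log2 ratio 5.75) and MAF4 (29 and 304, 3.15) were higher as well. The light-harvesting genes CAB2 (1692 and 24398 tags, 3.63) and LHCB2.3 (836 and 7967, 3.03) also ranked among the 10 highest, but both share sequence with near-identical copies. With shared tags divided equally CAB2 had a log2 ratio of 1.60 and LHCB2.3 of 2.38. The other genes among the 10 highest were ADPG1, which encodes a polygalacturonase of dehiscing tissue, with 1 and 108 tags and a ratio of 92.6 (16.3 to 3690), the small-peptide gene ROT4 (15 and 410 tags, 4.50), AT4G19430 (37 and 1488, 5.09), AT1G52820 (9 and 228, 4.37) and AT3G55240 (104 and 910, 2.90).

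The 10 genes with the lowest ratio included several of the phosphate response. PS2 (AT1G73010, chromosome 1, 27464528 to 27466348), a phosphatase gene induced by phosphate starvation, had 1748 tags in WT and 62 in ago1-27, a ratio of 0.0304 (0.0232 to 0.0392). The purple acid phosphatase gene PAP14 had a ratio of 0.0339 (0.00907 to 0.0896), the phosphate response gene SPX3 had 170 and 10 tags (log2 ratio −4.24), and IPS1, whose RNA sequesters miR399, had 206 and 16 (−3.87). The lowest ratio was that of AT3G05170 (371 and 4 tags, −6.59), followed by AT3G55920 (891 and 25, −5.35) and AT3G25240 (356 and 10, −5.31). The cell wall gene XTH17 (130 and 5, −4.79), AT1G23110 (354 and 16, −4.65) and AT3G46490 (561 and 40, −4.02) completed the group. With shared tags divided equally XTH17 stood at −3.44 and SPX3 at −3.28.

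Among 17325 genes with 100 or more tags, 384 were at least 2-fold higher in ago1-27 and 333 at least 2-fold lower. Counting error alone gave 0 and 0 such genes. Scaled by all tags of the library, 464 were higher and 268 lower, because the median log2 ratio of all genes moved from 0.01 to 0.11. The value lay within 0.5 of 0 on the log2 scale for 83.2% of genes. Short transcripts tended to be higher in ago1-27, with a median log2 ratio of 0.20 for 711 genes under 750 nt and −0.19 for 1996 genes of 3000 nt or more.

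Light-harvesting genes led the photosynthesis list, of which 18 of 22 members were higher in ago1-27 and 11 at least 2-fold. LHB1B2 had 123118 and 544327 tags, a ratio of 3.79 (3.77 to 3.81), and LHCB2.2 had 2296 and 17192 tags, a ratio of 6.42 (6.14 to 6.71). The 4 members that were lower were the genes of the Rubisco small subunit, the carbon-fixing enzyme, with a log2 ratio of −0.14 for RBCS1A, −0.50 for RBCS1B, −0.64 for RBCS2B and −0.46 for RBCS3B. The median of the list was 0.95 (0.28 to 1.92), at percentile 100 of random lists matched on mean tags and of lists matched also on length.

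Clock genes were higher as well, in 8 of 10 members, with a median of 0.93 (−0.17 to 1.51) at percentile 100. The log2 ratio was 1.14 for GI (4534 and 11654 tags), 1.51 for PRR5 (1852 and 6139) and 1.42 for CCA1 (61 and 192), while TOC1 stood at −0.18 (6324 and 6495) and ELF3 at −0.17. Salicylic acid and defence genes had a median of 0.32 (−0.04 to 1.36) at percentile 99.97, and 5 of 13 were at least 2-fold higher. The pathogenesis marker PR1 had a ratio of 2.69 (2.54 to 2.86), and the regulators WRKY70 and WRKY33 had ratios of 3.22 (3.09 to 3.35) and 2.04 (1.97 to 2.12). In the last 500 nt of the transcripts alone the defence list lay at percentile 92.2, inside the central range.

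Heat shock genes were lower in ago1-27, with a median of −1.53 (−2.65 to 0.45) at percentile 0 over 7 counted members, 5 of them at least 2-fold lower. HSP70 had 5765 and 1375 tags, a ratio of 0.204 (0.193 to 0.217), HSP90.1 6811 and 2746 tags, a ratio of 0.346 (0.330 to 0.361), and the heat shock factor HSFA2 354 and 126 tags, a ratio of 0.305 (0.247 to 0.375). Anthocyanin and flavonoid genes had a median of −0.29 (−1.48 to −0.17) at percentile 2.385, close to the edge of the central range, and all 11 were below 0. The list lay inside that range at percentile 2.63 with median-of-ratios scaling and 4.64 with 100 or more tags. The chalcone synthase gene TT4 led them with 7025 and 2138 tags and a ratio of 0.261 (0.248 to 0.274), followed by FLS1 with a ratio of 0.501 (0.458 to 0.549) and TT5 with 0.666 (0.619 to 0.716). Flower markers had a median of −1.39 (−3.50 to 0.72) at percentile 0.02 over 6 counted members, all with few tags. SEP3 had 159 and 41 tags and SEP1 135 and 51, whereas AGL8 had 158 and 304.

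**Figure D3:**
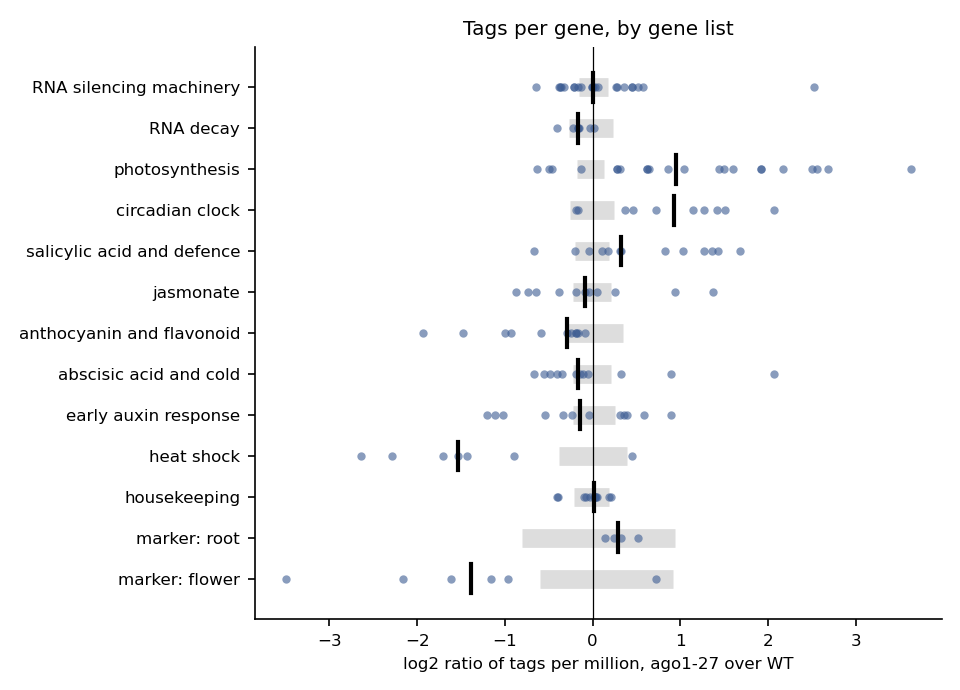
Log2 ratio of tags per 1000000, ago1-27 over WT (x axis), for the members of each list fixed beforehand (y axis), where each dot is a gene with 10 or more tags, the black bar is the median of the list and the grey bar the central 95% of medians of 10000 random lists. The medians of photosynthesis (0.95) and circadian clock genes (0.93) lie right of their grey bars, and those of heat shock genes (−1.53) and flower markers (−1.39) left of them.

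The remaining lists lay inside the central range, except the miRNA targets over all their sense tags. RNA silencing genes had a median of −0.00 (percentile 41.16). Among them AGO10 stood at 0.28, SDN1 at 0.57 and RDR6 at −0.65, which became 0.019 without its most abundant position. RNA decay genes had a median of −0.16 (percentile 10.16), with the exonuclease genes XRN4 at 0.01 and XRN3 at −0.22, and AT1G76630 at −0.41. Jasmonate genes had a median of −0.08 (percentile 23.04), with the storage protein gene VSP1 at 1.38, PDF1.2 at 0.94, AOC2 at 0.25 and LOX2 at 0.04. Genes of abscisic acid and cold had a median of −0.17 (percentile 7.05), but the cold-induced COR15B stood at 2.06 and COR15A at 0.90, with COR47 at −0.11. Early auxin genes had a median of −0.14 (percentile 9.81), which turned to 0.13 (percentile 84.34) over the 10 members with 100 or more tags, with IAA19 at −1.20, SAUR15 at −1.03, IAA7 at −0.34 and IAA2 at 0.39.

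Housekeeping genes had a median of 0.02 (percentile 63.07), with UBQ10 at 0.02, ACT2 at −0.39 and GAPC2 at −0.40. UBQ10 stood at −0.0088 with shared tags divided equally. Root markers had few tags and a median of 0.29 (percentile 70.97) over 4 counted members, including CASP1 with 58 and 85 tags and CASP2 with 23 and 32. Of the seed storage markers only CRA1 reached 10 tags (18 in WT and 16 in ago1-27), and of the senescence markers NYE1 (1206 and 1470 tags) and SAG13 (153 and 496) did, too few for a median. The miRNA targets as a list over all their sense tags had a median of 0.08 (percentile 98.08), just above the central range of −0.06 to 0.08. The median was −0.0045 (percentile 44.57) with shared tags divided equally, and the percentile was 94.38 with 100 or more tags. The list lay further out with random genes matched also on length (percentile 99.95) and in the last 500 nt (percentile 99.79).

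The third comparison describes where tags lay along transcripts, known features of degradome data. Tags lay nearer to the 3′ end in ago1-27. The 3′ UTR held 21.1% of transcript tags in WT and 28.3% in ago1-27, the coding sequence 74.6% and 67.9%, and the 5′ UTR 4.34% and 3.81%. The 3′ UTR share was higher in ago1-27 in 15631 of 16562 transcripts (94.4%), with a median difference of 5.79 percentage points (5.70 to 5.89). Upstream of the stop codon, where a terminating ribosome halts decay, the density 16 and 17 nt away was 4.72 times the mean further upstream in WT and 3.06 times in ago1-27. Upstream of exon junctions, the footprint of the exon junction complex at 26 to 30 nt was 3.15 times the mean further upstream in WT and 3.53 times in ago1-27. The reading frames held 30.7%, 35.8% and 33.4% of coding tags in WT and 30.6%, 36.1% and 33.2% in ago1-27.

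**Figure D4:**
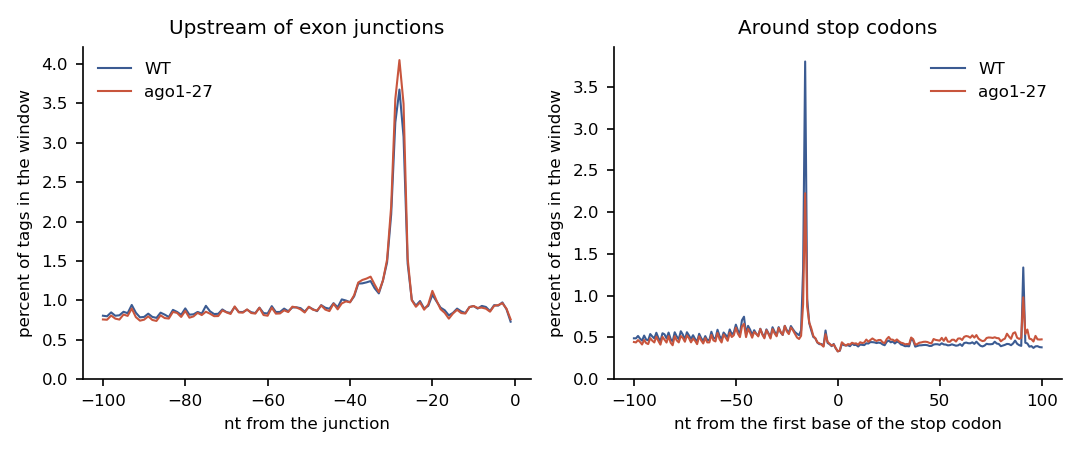
Percent of the tags in each window (y axis) by distance in nt from the exon junction (left, x axis) and from the first base of the stop codon (right, x axis), summed over transcripts, with WT in blue and ago1-27 in red. The peak 26 to 30 nt upstream of junctions stood at 3.15 times its surroundings in WT and 3.53 times in ago1-27, and the peak upstream of stop codons at 4.72 and 3.06 times.

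The fourth comparison concerns MIR precursors, the hairpin RNAs from which miRNAs are cut, where tags at the ends of the mature miRNA mark processing cuts. MIR172b had 98 and 825 tags, a ratio of 7.22 (5.85 to 8.99), but 85 and 797 of them lay at 1 position with the same counts in MIR172e, so these 2 precursors were not told apart. MIR156c had 2217 and 4248 tags, a ratio of 1.64 (1.56 to 1.73), of which 2071 and 4043 lay at a position with the same counts in MIR156a, MIR156b, MIR156d, MIR156e and MIR156f, so the value describes the shared miR156 sequence. Some precursors of copper-responsive miRNAs were lower, with a ratio of 0.270 (0.256 to 0.283) for MIR408, 0.240 (0.208 to 0.275) for MIR398b and 0.256 (0.215 to 0.304) for MIR398c. With fewer tags, MIR398a (40 and 20, ratio 0.429, 0.237 to 0.751) and MIR397a (32 and 8, ratio 0.214, 0.0853 to 0.475) were lower as well. The intervals of MIR857 (9 and 11 tags) and MIR397b (6 and 3) held 1. MIR400 had 345 and 46 tags, a ratio of 0.114 (0.0821 to 0.156). For MIR408, MIR398b, MIR398c and MIR400 the ratio covers all tags of the precursor, and the position with the most tags was not an annotated end. At the ends lay 1551 and 322 tags of MIR408, 75 and 31 of MIR398b, and 7 and 0 of MIR400. Their ratios therefore do not describe processing cuts alone. In total 63763 tags lay on MIR genes in WT and 63810 in ago1-27, of which 58.4% (58.1 to 58.8) and 57.1% (56.7 to 57.5) started at an end of the mature miRNA or its star strand. The MIR genes named here were chosen after their values were seen, and family members such as MIR398b and MIR398c share tags.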

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

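The tests of tags over whole target transcripts, of a mislabelled sample, of a few abundant genes, of a shift along the whole transcript and of random breakage were chosen after the results were seen, while the other 4 tests had their bounds written before their own result was seen.

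Several parts of the libraries that no comparison used held a larger share of the ago1-27 than of the WT library, and are given here for that reason alone. Among tags of 20 nt or more, nuclear rRNA took 2.18% in ago1-27 and 1.86% in WT. snoRNA took 5.82% and 5.08%. snRNA took 0.0198% and 0.00908%. tRNA took 0.00527% and 0.00467%. Other nuclear genes in sense took 0.854% and 0.701%, and other nuclear sequence 3.52% and 3.02%. Tags with no exact match made up 8.26% in ago1-27 and 5.96% in WT. Tags of 19 nt made up 1.89% of all tags in ago1-27 and 1.34% in WT. Each share depends on the others, and chloroplast tags (17.6% against 25.2% in WT) and mitochondrial tags (3.12% against 3.34%) had a smaller share in ago1-27.

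Cleavage-site tags of AGO1, of the miR393 and miR169 targets and of most other targets with a counted site were lower in ago1-27. Fewer tags over the whole target transcripts would leave the share at the site level, but the median log2 ratio of that share was −0.74 (−1.06 to −0.39). The shift of the ago1-27 library toward 3′ ends would place the sites among other positions at the same distance from the transcript end, but they lay at percentile 0 of such positions, and an exchange of the libraries is excluded by the A994V change, present in 98.0% of AGO1 tags in the library labelled ago1-27. That weakened AGO1 cuts these targets less is a hypothesis these values leave open, found and examined on the same pair of libraries. It was not separated from other sources of fewer site tags, such as differences in miRNA levels or in decay of the cut fragments. Any difference in preparation between the pooled libraries is confounded with genotype and stays open.

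The 3′ UTR held more of the tags of most transcripts in ago1-27. A few abundant genes could not give this, since 94.4% of transcripts had the higher share in ago1-27. The shift also appeared inside coding sequences, whose last part of 3 equal parts held 4.64 percentage points more of the coding tags in ago1-27, so that a shift along the whole transcript may be the source. Random breakage of RNA was examined by whether both the junction and the stop codon peaks were diluted in ago1-27. The junction peak was higher (ratio 1.12) and the stop codon peak lower (ratio 0.648). Breakage could also remove upstream ends without diluting either peak, so these measures cannot tell it apart from other sources. A difference in decay between the genotypes and a difference in library preparation both stay open and untested.

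Light-harvesting and clock genes had more tags in ago1-27. Dividing the tags shared between near-identical copies equally left the photosynthesis median at 0.95 (0.31 to 1.62). The lower bound lay close to the limit of 0.3 set for this test. That median lies between the values of LHCB6 (0.86) and LHCA1 (1.04), so it can stay level while single copies fall. CAB2, for example, went from 3.63 to 1.60. Shared tags therefore did not account for the list median, but their part in the ratios of single copies was not settled. Short transcripts did not account for that median either, since the list lay at percentile 100 of random genes matched also on length. A different time of day at collection may contribute. Day-phase genes had a median 0.23 above that of dusk-phase genes, between the limits of 0.2 and 0.5 written before this difference was seen. Both lists, however, were chosen after the values of some members were seen. They are short, and the day-phase members ran from 0.45 (PRR3) to 1.90 (DREB1A), so the difference depends on which genes were listed. Collection time and genotype cannot be told apart here. Altered growth or light response of the mutant is an untested biological alternative.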

How the results depend on the processing

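No difference here has a replicate check, and the alternatives with all tags in the last 500 nt, equal sharing of tags within the lists, matching on length or distance, no limit on genome places and a denominator of 250 nt were chosen after the data were seen. The cleavage-site results kept their direction under every alternative run: the median log2 ratio over the sites ranged from −1.18 to −0.87, always at percentile 0, and the median log2 ratio of shares was −0.74 or lower in each. Sites at least 2-fold higher numbered 2 when scaled by all tags and 0 with 50 or more tags at the site. Genes at least 2-fold higher and lower numbered 794 and 629 with 10 or more tags, and 191 and 166 with 500 or more, where other numbers of genes entered. Of 125 values for 26 named site results, 110 moved by less than the counting interval and 15 by more, all with the same sign. Of 336 values for 84 named gene results, 310 moved by less than the interval and 24 by more with the same sign, while RDR6 reversed to 0.019 without its most abundant position and UBQ10 to −0.0088 with shared tags divided equally. Early auxin genes reversed to 0.13 with 100 or more tags. Equal sharing turned the housekeeping median to −0.021 and also reversed the median of the miRNA targets over all tags to −0.0045 (percentile 44.57), and with 100 or more tags that list lay at percentile 94.38. Anthocyanin genes left the outer range at percentile 2.63 with median-of-ratios scaling and 4.64 with 100 or more tags. In the last 500 nt, the medians were 0.23 for RNA decay (percentile 53.1), 0.30 for jasmonate (77.05) and 0.22 for RNA silencing (47.09). Housekeeping genes had 0.31 (percentile 83.92), so these lists stayed inside the central range although their medians were higher. Anthocyanin genes had −0.12 (percentile 1.95) and the miRNA targets 0.33 (99.79). The percentiles were 92.2 for defence and 2.49 for abscisic acid and cold genes. With each transcript weighted equally, ago1-27 minus WT was 0.199 percentage points for frame 1, 5.89 for the 3′ UTR and −4.85 for the coding share, and the ratios were 1.08 at junctions and 0.647 at stop codons. Within 1 nt of the ends, 67.8% of MIR tags in WT and 65.4% in ago1-27 lay at mature or star ends. The cause of these movements was not tested. No paired analysis was possible because each genotype has 1 pooled column. For the same reason DESeq2, a filter by expression, a replicate block and omission of each replicate were not run. Root markers gave no value at 100 or more tags. Depth limits the flower and root markers and sites such as that of CUC1, with 11 tags in WT.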

Other observations

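The 5 gene lists below and the test of the time of day were chosen after the values of some members were seen. The places of these lists among random lists therefore describe the lists and are not independent evidence.

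Genes induced by phosphate starvation were lower in ago1-27 beyond the 10 lowest genes. A list of 15 further phosphate starvation genes had a median log2 ratio of −0.99 (−1.43 to −0.73), all 15 were lower, and the list lay at percentile 0 of random lists. The galactolipid synthase gene MGDC, which replaces phospholipids under phosphate shortage, had 358 tags in WT and 74 in ago1-27, a ratio of 0.177 (0.136 to 0.228). AT5G03545, a relative of IPS1, had a ratio of 0.183 (0.137 to 0.242). The sulfolipid genes SQD2 and SQD1, the most abundant members, had ratios of 0.561 (0.536 to 0.588) and 0.601 (0.573 to 0.630). The FLC family of floral repressors had 6 of 6 members higher in ago1-27, but its median of 1.79 (0.26 to 5.75) was set by FLC, MAF4 and MAF5, which prompted the list, so its place among random lists is not informative. The other members differed little, as AGL31 had a log2 ratio of 0.26, MAF1 had a ratio of 1.31 (1.24 to 1.37) and MAF3 one of 1.35 (1.26 to 1.43).

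Genes of copper proteins and copper uptake went both ways, with 7 of 11 higher in ago1-27 and a median of 0.36 (−0.88 to 0.85) at percentile 99.73. The copper/zinc superoxide dismutase genes CSD2 and CSD1, both miR398 targets, had log2 ratios of 1.24 and 0.85, and their chaperone gene CCS 0.41. The iron superoxide dismutase gene FSD1 stood at −0.71, the copper transporter gene COPT2 at −0.94 and the copper chaperone gene CCH at −0.88. The abundant plastocyanin gene DRT112 stood at −0.15. Of the day-phase genes, 6 of 6 were higher in ago1-27 with a median of 1.00 (percentile 100), led by DREB1A with 105 and 459 tags and AT3G54500 with 219 and 869. Of the dusk-phase genes 3 of 4 were higher with a median of 0.77 (percentile 99.77), among them GRP7 at 0.85, CCR1 at 0.93 and CAT3 at 0.69, while BOA stood at −0.40.

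In both libraries, tags with 1 mismatch to the AGO1 coding sequence also gave a silent difference from the reference, G210A (Q70Q). Coding bases are counted from the start codon of the longest isoform. The difference was present in all 19 WT tags counted over the position, and in 25 ago1-27 tags against 4 with the reference base. Whether the changed tags also match another place in the genome was not examined. A variant in AGO1 itself is therefore not established. Downstream of stop codons a single position, 91 nt from the first base of the stop codon, held 1.34% of the tags of the window of the stop codon profile in WT and 0.979% in ago1-27. The profile is a sum over transcripts, and how many of them gave this position was not examined.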
